A study of Mus musculus with 12 samples.

How the data were processed

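Total RNA from the sorted G1 fraction of NIH3T3 cells was measured on 12 whole-transcript mouse arrays, 3 of untreated cells and 2, 3, 2 and 2 of cells kept in 1 mM DFMO for 12, 24, 48 and 96 h. Per the labels' protocols, the drug was added a day after seeding, and labelled cDNA was made with a whole-transcript kit. The series text gives 0 h for the untreated cells, and no untreated culture of a later time was analysed here. The labels call the arrays biological replicates, and their number limits the precision.

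The authors deposited 1 table of log2 values, 1 row per transcript cluster, summarised and normalised before deposit. RMA, which corrects background, normalises by quantiles and summarises probes, and the Partek software are named per the submitters' processing notes, with no versions. The deposited log2 values ran from 2.53 to 13.18, and the array medians from 4.13 to 4.20. Quantile normalisation forces the arrays to share 1 distribution, so a change of all transcripts in 1 direction would be hidden. Background stays in the values, so low transcripts sit on a floor and folds from or to it are too small. The median untreated level of 20 leukocyte markers, which fibroblasts should mostly lack, was 3.65.

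Clusters were named through the platform annotation, with symbols looked up by Entrez identifier in the RefSeq table of assembly GRCm38.p6. Of 35399 clusters, 21789 had 1 symbol, 1621 several and 11989 none in that annotation. For 21698 clusters the identifier was found, and 0 symbols needed an update. A gene with more than 1 cluster (999 genes) was represented by the one with the highest mean over all arrays, which left 19938 genes. Clusters with several symbols or none were left out of the gene tests and tested only as an alternative. All 12 arrays were used, and 0 columns of values lacked a sample. No coordinates are given because the array's genome build is not given in the sources used here.

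A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with default settings). Each time was compared with untreated cells, each time with the time before it, and all 4 times together with untreated cells by limma's F test. All p-values are two-sided and adjusted by Benjamini and Hochberg within a comparison, and a gene was called at an adjusted p under 0.05. Log2 changes are given with limma's standard errors, and folds are those of the log2 values. In simulated data made from the means and spreads of these arrays, with 200 of 19938 genes changed in each of 10 runs, the comparison at 24 h recovered 81.8% of genes changed 2-fold and 44% of those changed 1.5-fold. The comparisons at 48 h and 96 h recovered 75.2% and 72.3% at 2-fold and 6.12% each at 1.25-fold, with 3.2 and 4.4 false calls per run on average. These runs called 82.8 and 79.1 genes on average, against 1160 and 4372 in the data. The adjusted threshold is less strict when more genes change, so these shares do not describe the real comparisons at 48 h and 96 h. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.

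The groups, the comparisons, the 22 gene lists (675 of 723 members measured), the rule for named genes and the main alternatives were chosen before the data were examined. The rule named, at each time, the 6 genes with the largest rise and the 6 with the largest fall among those called whose treated arrays all lay beyond all untreated arrays. It also named any member of the polyamine list, up to 4 members of each other list with the smallest F test p, and for each step the 3 largest rises and falls. Genes without a proper symbol were to be passed over, which applied to 0 genes among the largest changes at each time. For the steps the genes passed over were not counted. Genes named outside this rule are marked as chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01, adjusted over 88 tests (22 lists at 4 times), then with a correlation estimated per list and with fry. The PValue of fry asks whether a list moves in 1 direction on balance and its mixed value whether members change in either direction, and neither compares a list with other genes. A count adjusted over the list alone comes from the limma p-values of that list's members.

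The labels number the replicates, and whether equal numbers pair the arrays was checked from deviations from the group means. For 24 h against untreated the 3 same-number pairs correlated across genes with r of 0.153, 0.287 and 0.581, all over the 0.1 asked for. Some pairs of unlike number passed it too, untreated replicate 1 with 24 h replicate 2 (0.235) and untreated replicate 2 with 24 h replicate 1 (0.126). The remaining ones were negative, down to -0.423. The check therefore cannot show that the numbers pair these arrays, and the blocked count is given beside the main one. The rule asks for 3 pairs, so it could not be met in the other comparisons, where 2 numbers are shared, and pairing stays open there as well. Every comparison against untreated cells shares the same 3 arrays. Correlations between times were therefore set beside those of 100 simulations of unchanged groups with these group sizes and independent arrays.

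The alternatives tried were a replicate block, eBayes with trend and robust on, array weights, a filter that kept 10331 genes above the median of all values (4.17) in at least 2 arrays, and quantile normalisation again. Others were centring each array on its median, all clusters tested together, the mean of a gene's clusters, only the groups compared, a fold of at least 1.5, an adjusted p under 0.01, and each array left out in turn. After the data had been seen, 3 arrays that deviated together (untreated replicate 3, 12 h replicate 2 and 24 h replicate 3) were entered as a batch block and, separately, left out.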

Results

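Transcript levels were measured in NIH3T3 cells, an established line of mouse fibroblasts, during treatment with difluoromethylornithine (DFMO). DFMO inhibits ornithine decarboxylase, the enzyme that makes putrescine from ornithine, and so depletes cells of polyamines. Cells in G1 were collected by sorting before the drug and at 12, 24, 48 and 96 h of exposure to 1 mM, to follow the transcriptional response to polyamine depletion. There were 3 untreated arrays, 2 at 12 h, 3 at 24 h, 2 at 48 h and 2 at 96 h, each described in the labels as a biological replicate. Each of the 12 arrays gave values for 35399 transcript clusters, and 19938 genes entered the tests. Array medians lay between 4.13 and 4.20 log2 units, and replicate arrays correlated across genes with r of 0.994 to 0.998. The untreated arrays belong to 0 h, so hours in culture changed together with exposure to the drug in every comparison. Cell density, for which no values were available here, may have changed as well.

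Odc1, the gene of ornithine decarboxylase and so of the drug's target, had a mean log2 level of 9.71 ± 0.09 (SD, n = 3) in untreated cells. Its log2 change was 0.07 at 12 h, 0.04 at 24 h and 0.03 at 48 h, and at 96 h it fell by 0.68 ± 0.16 (SE, limma adjusted p = 0.0133, n = 2 against 3). Without replicate 1 or without replicate 2 of the 96 h group the call was lost, at log2 changes of -0.72 and -0.63. DFMO acts on the enzyme, so the transcript does not report inhibition.

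Among the other 23 polyamine genes measured, Oaz2 and Smox passed the test over all genes as lower at 48 h and 96 h. Adjusted over the list alone, Oaz2 was already lower at 24 h, as given below. Oaz2 encodes an antizyme, a protein that binds ornithine decarboxylase and sends it for degradation. It fell by 1.20 ± 0.15 at 48 h (adjusted p = 0.00278) and by 1.18 ± 0.15 at 96 h (adjusted p = 0.000431). Smox, which encodes spermine oxidase, fell by 1.28 ± 0.27 at 48 h (adjusted p = 0.0244) and by 1.48 ± 0.27 at 96 h (adjusted p = 0.00326). At 96 h Azin2, which encodes an inhibitor of antizyme, rose by 0.66 ± 0.11 (adjusted p = 0.00168), and Atp13a2, a lysosomal polyamine exporter, rose by 0.64 ± 0.10 (adjusted p = 0.0014). Eif5a, the translation factor that carries the spermidine-derived residue hypusine, fell by 0.37 ± 0.06 (adjusted p = 0.00253). In all, 0 of 24 members rose and 2 fell at 48 h, and 2 rose and 6 fell at 96 h, with the same counts at both times when adjusted over the list alone. The measured members as a whole were not called at any time by the camera test, which asks for a shift in 1 direction. The mixed test of fry called the list at 24, 48 and 96 h (adjusted p = 3.74e-07, 2.17e-06 and 6.82e-07). It did not call the list at 12 h (0.305). Of all 22 lists, this mixed test called 6, 18 and 22 at 24, 48 and 96 h. Of the 31 members fixed for this list, Oaz1, Amd1, Amd2, Sms, Paox, Mat2a and Ahcy were not measured. The Smox call at 48 h ended without untreated replicate 1 (-1.20), untreated replicate 2 (-1.25), 48 h replicate 1 (-0.99) or 48 h replicate 2 (-1.57), and 3 members remained lower at 96 h without 96 h replicate 2.

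**Figure D1:**
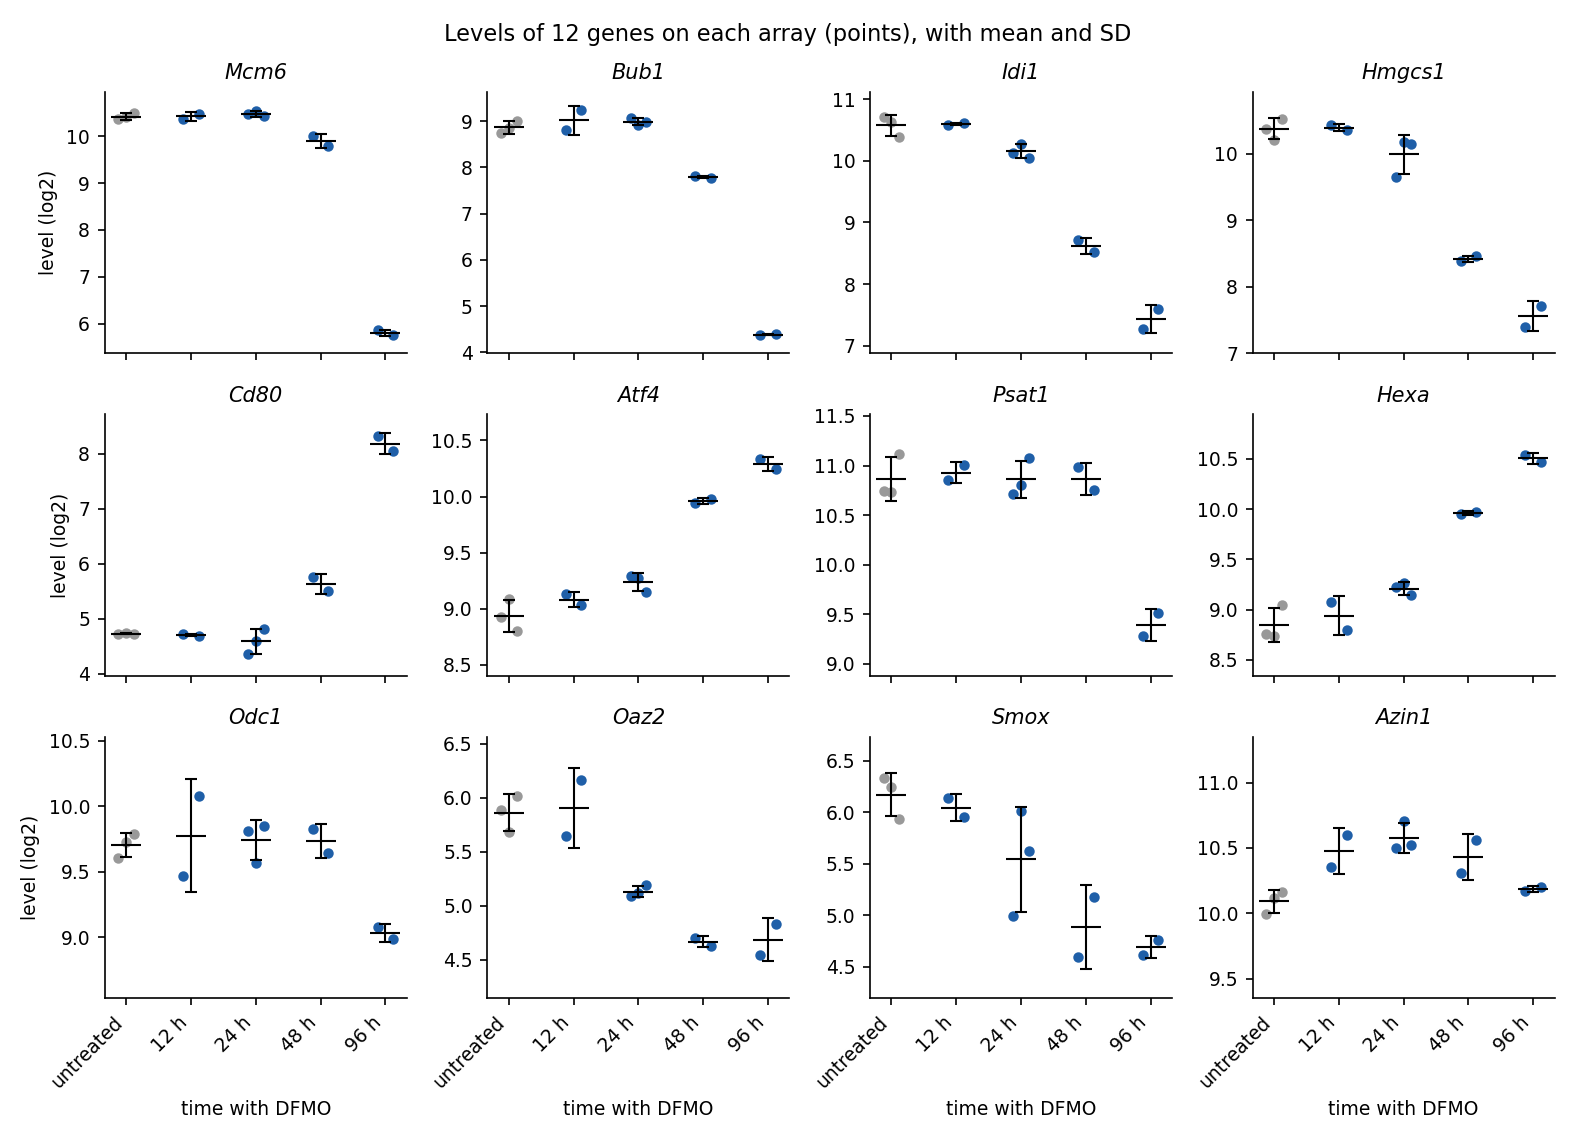
Log2 level of 12 genes against hours of DFMO, with 1 point per array, and the mean and SD of each group; the vertical axes differ between panels. Mcm6 went from a mean of 10.4 to 5.81 and Atf4 from 8.94 to 10.3 between untreated cells and 96 h, while the mean changes of Odc1 up to 48 h lay between 0.03 and 0.07.

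At 12 h no gene passed the test, and 2 gene lists were called by camera. The unfolded protein response list (29 genes, folding factors and their regulators) had a median log2 change of -0.12 and a camera adjusted p of 0.00196, which became adjusted p = 0.444 with an estimated correlation. The immediate early list (31 genes induced by growth factors and stress) had a median of 0.10 and an adjusted p of 0.00409, against adjusted p = 0.367 with an estimated correlation. In both lists 0 members passed the test, over all genes and adjusted over the list alone. By limma 0 of 19938 genes changed, with a smallest adjusted p of 0.836, and 741 had an unadjusted p under 0.05 where 997 would arise by chance. The unfolded protein response call ended without untreated replicate 3 (adjusted p = 0.498) or 12 h replicate 2 (0.26), and the immediate early call without 12 h replicate 1 (0.0567). With untreated replicate 3, 12 h replicate 2 and 24 h replicate 3 all left out, a set chosen after the data were seen, the unfolded protein response list changed sign (adjusted p = 0.576). In simulated data with 200 changed genes this comparison recovered 72% of those changed 2-fold and 30.7% of those changed 1.5-fold.

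At 24 h the cholesterol biosynthesis list was called lower by camera with its preset correlation. The 20 measured members, enzymes of the mevalonate and sterol pathway and their regulators, had a median log2 change of -0.33 and a camera adjusted p of 2.57e-09, which became adjusted p = 0.336 with an estimated correlation. None passed over all genes, and 6 were lower when adjusted over the list alone (Mvk, Pmvk, Mvd, Idi1, Fdps and Nsdhl, where Mvk, Pmvk and Mvd were chosen after their values were seen). Idi1, the isomerase of isopentenyl diphosphate, changed by -0.43 and Nsdhl, a sterol dehydrogenase, by -0.63. Of the polyamine genes, adjustment over the list alone called Oaz2 (-0.73 ± 0.14), Azin1 (0.49 ± 0.09) and Azin2 (0.44 ± 0.10), at adjusted p values over all genes of 0.261, 0.262 and 0.384.

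A further 6 lists were called at 24 h by camera with its preset correlation, and none of these calls held with an estimated one. Medians were -0.16 for the unfolded protein response (adjusted p = 0.000437, and adjusted p = 0.444 with an estimated correlation) and -0.14 for glycolysis and hypoxia (0.00305, and adjusted p = 0.444 with an estimated correlation). Heat shock genes had a median of -0.11 (0.00477, and adjusted p = 0.444 with an estimated correlation), with 1 member higher and 5 lower when adjusted over the list alone. The adipocyte list had a median of -0.06 and a mean of -0.13 (0.00409, and adjusted p = 0.175 with an estimated correlation). Genes responsive to SRF, YAP and TGF-beta had a median of 0.10 (0.00332, and adjusted p = 0.805 with an estimated correlation) and immediate early genes one of 0.04 (0.0233, and adjusted p = 0.444 with an estimated correlation). By limma 0 genes changed at 24 h, with a smallest adjusted p of 0.229 and 1579 genes at an unadjusted p under 0.05, and with all 35399 clusters tested together 11 passed. Whether replicate numbers pair the untreated and 24 h arrays was not settled. With the number as a block limma again called 0 genes, with 2040 at an unadjusted p under 0.05. Without untreated replicate 3 the unfolded protein response (adjusted p = 0.135), glycolysis (0.124) and heat shock (0.13) calls ended. Others ended without 24 h replicate 1 (glycolysis 0.052, immediate early 0.211), 24 h replicate 3 (heat shock 0.0809, immediate early 0.0533) or untreated replicate 1 (SRF and YAP 0.14, immediate early 0.0749).

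At 48 h genes of the cholesterol pathway, of DNA replication and of mitosis fell. Nsdhl, with a mean log2 level of 9.23 in untreated cells and 6.94 at 48 h, fell by 2.28 ± 0.18 (SE, limma adjusted p = 0.000494, n = 2 against 3). Idi1 fell by 1.97 ± 0.12 (adjusted p = 0.000399), Hmgcs1, the synthase of hydroxymethylglutaryl-CoA, fell by 1.96 ± 0.16 (adjusted p = 0.000672), and Insig1, a sterol-regulated brake on SREBP processing, by 1.79 ± 0.15 (adjusted p = 0.000672). Lss, lanosterol synthase, fell by 1.76 ± 0.24 (adjusted p = 0.00359). Pfkl, the liver-type phosphofructokinase, fell by 1.62 ± 0.26 (adjusted p = 0.00861), a call that ended without 48 h replicate 1 (-1.24).

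The genes with the largest rises at 48 h were of mixed function. The histone gene H2bc4 rose by 1.99 ± 0.23 (3.98-fold, adjusted p = 0.0018) and Sulf2, an extracellular heparan sulfate 6-O-endosulfatase, by 1.75 ± 0.13 (3.37-fold, adjusted p = 0.000461). Slc9a9, an endosomal sodium-proton exchanger, rose by 1.71 ± 0.20 (adjusted p = 0.00197) and Tmem150a by 1.60 ± 0.17 (adjusted p = 0.00134). Txnip, the thioredoxin-interacting protein, rose by 1.52 ± 0.21 (adjusted p = 0.00409) and Chchd5 by 1.47 ± 0.11 (adjusted p = 0.000461). By limma 1160 of 19938 genes changed at 48 h, 528 higher and 632 lower, of which 253 and 332 by at least 1.5-fold. The count was 755 without untreated replicate 1, 642 without untreated replicate 2, and 375 and 412 without replicate 1 and replicate 2 of the 48 h group, which then rests on 1 array assumed to vary like the others. It was 2194 with array weights. Fallen genes did not outnumber risen ones in every setting, with 644 higher and 552 lower with centred arrays, 810 and 732 with the replicate block, and 465 higher of 918 without untreated replicate 3. With 3 arrays that deviated together, chosen after the data were seen, the numbers were 628 and 527 with them left out and 755 and 753 with them as a block.

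Of the gene lists, cholesterol biosynthesis had 19 of 20 members lower and 0 higher at 48 h (19 adjusted over the list alone), with a median of -1.49 and a camera adjusted p of 4.91e-27, against adjusted p = 0.0955 with an estimated correlation. Fdps, farnesyl diphosphate synthase, fell by 1.48 ± 0.11 and Cyp51, lanosterol demethylase, by 1.35 ± 0.13. Of 46 DNA replication and S phase genes, 30 fell and 0 rose (39 and 0 adjusted over the list alone), with a median of -0.71 (4.88e-27, and adjusted p = 0.126 with an estimated correlation). Mcm5, a subunit of the replicative helicase, fell by 0.82 ± 0.11 (adjusted p = 0.00357). Of 51 mitosis and G2/M genes, 32 fell and 0 rose (44 and 0 adjusted over the list alone), with a median of -0.80 (4.36e-31, and adjusted p = 0.12 with an estimated correlation). Among them Bub1b, a spindle checkpoint kinase, fell by 1.39 ± 0.12 and Tpx2, a spindle assembly factor, by 0.73 ± 0.07. Without replicate 1 and without replicate 2 of the 48 h group, the fallen replication genes numbered 16 and 12 and the fallen mitosis genes 21 and 20.

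The ATF4, p53 and lysosome lists were called higher at 48 h, with most members not past the test singly. In the ATF4 and amino acid response list (41 genes), 7 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.44 and a camera adjusted p of 6.13e-09, against adjusted p = 0.336 with an estimated correlation. Atf4 itself, the transcription factor translated more when eIF2 alpha is phosphorylated, rose by 1.02 ± 0.08 (2.03-fold, adjusted p = 0.000672), and Ddit3, which encodes the stress factor CHOP, by 1.28 ± 0.21 (adjusted p = 0.00798, lost without 48 h replicate 1 at 1.09). Of 34 p53 target genes, 7 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.28 (4.62e-08, and adjusted p = 0.141 with an estimated correlation). Cdkn1a, a member of this list and of the list of cell cycle inhibitors, was not tested, because its cluster carries a second symbol. Cd80, a costimulatory surface protein, rose by 0.91 ± 0.13 (adjusted p = 0.00443) and Ercc5, a nuclease of excision repair, by 0.56 ± 0.08 (adjusted p = 0.00457). Of 36 lysosome and autophagy genes, 4 rose and 0 fell (7 and 1 adjusted over the list alone), with a median of 0.23 (0.00027, and adjusted p = 0.467 with an estimated correlation), and Hexa, a lysosomal hexosaminidase, rose by 1.11 ± 0.10 (adjusted p = 0.000963). The 7 risen ATF4 genes numbered 2 without untreated replicate 1, 2 without untreated replicate 2, 1 without 48 h replicate 1 and 3 without 48 h replicate 2. The 7 p53 targets numbered 4 without untreated replicate 2 and 4 and 2 without 48 h replicates 1 and 2, and the 4 lysosome genes 2, 2, 2 and 1 without untreated replicates 1 and 2 and 48 h replicates 1 and 2.

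Another 4 lists were called lower at 48 h. The unfolded protein response list had 1 member higher and 8 lower of 29 (1 and 13 adjusted over the list alone), with a median of -0.22 (0.000834, and adjusted p = 0.444 with an estimated correlation). Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, fell by 1.00 ± 0.12 (adjusted p = 0.00195) and Dnajb11, another, by 0.53 ± 0.07 (adjusted p = 0.00249). Of 22 heat shock genes, 8 fell and 0 rose (13 and 2 adjusted over the list alone), with a median of -0.28 (9.07e-05, and adjusted p = 0.336 with an estimated correlation). Of 31 glycolysis and hypoxia genes, 6 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.16 (0.00239, and adjusted p = 0.444 with an estimated correlation). Of 20 adipocyte genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.06 and a mean of -0.30 (0.00409, and adjusted p = 0.175 with an estimated correlation). The members named here make fatty acids, and Elovl6, a fatty acid elongase, fell by 1.20 ± 0.14, Acly, ATP citrate lyase, by 1.16 ± 0.11 and Scd2, a stearoyl-CoA desaturase, by 1.40 ± 0.20. Without 48 h replicate 1 the fallen members numbered 3 for the unfolded protein response, 0 for heat shock and 2 for glycolysis, and without 48 h replicate 2 they numbered 4, 3 and 2. The heat shock count was 5 without untreated replicate 2 and 5 without untreated replicate 3.

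The remaining 11 lists other than polyamine metabolism were not called by camera at 48 h. Of 33 NRF2 and oxidative stress genes 5 fell and 1 rose (7 and 2 adjusted over the list alone), with Tkt, a transketolase, lower (-0.90 ± 0.09) and Pgd, of the same pentose phosphate pathway, as well (-0.75 ± 0.09), at a camera adjusted p of 0.176. The directional test of fry called this list (adjusted p = 0.0433). Of 22 aminoacyl-tRNA synthetase genes 2 rose and 0 fell (3 and 1 adjusted over the list alone), with a median of 0.09 and a camera adjusted p of 0.0588. Among 24 G1 cyclins and inhibitors 1 rose and 1 fell, and 1 member rose in each of the matrix, SRF and YAP, and immediate early lists with 0 lower, Timp2, a metalloproteinase inhibitor, by 0.46 ± 0.06 among the matrix genes. By limma 0 members changed in the ribosome biogenesis, interferon, NF-kB, leukocyte, and epithelial and endothelial lists. The 5 fallen NRF2 genes numbered 3 without untreated replicate 2 and 2 and 2 without 48 h replicates 1 and 2.

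At 96 h the genes with the largest falls were proliferation genes. Pclaf, a PCNA-associated factor, went from a mean log2 level of 9.88 to 4.09 and fell by 5.78 ± 0.18 (SE, 55.0-fold, limma adjusted p = 5.92e-08, n = 2 against 3). Uhrf1, which maintains DNA methylation, fell by 5.10 ± 0.12 (34.2-fold, adjusted p = 2.36e-08), cyclin A2 (Ccna2) by 4.79 ± 0.17 (27.6-fold, adjusted p = 1.19e-07), and the helicase subunit gene Mcm6 by 4.62 ± 0.08 (24.5-fold, adjusted p = 3.42e-09). Mcm5 fell by 4.57 ± 0.11 (23.8-fold, adjusted p = 2.36e-08) and the checkpoint kinase gene Bub1 by 4.49 ± 0.12 (22.4-fold, adjusted p = 2.7e-08).

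The genes with the largest rises at 96 h were of mixed function. Dcn, the matrix proteoglycan decorin, rose by 4.37 ± 0.31 (20.6-fold, adjusted p = 1.05e-05), Ces2e, a carboxylesterase, by 4.30 ± 0.19 (19.7-fold, adjusted p = 5.02e-07), and Ptprv, a receptor-type tyrosine phosphatase, by 3.71 ± 0.09 (13.1-fold, adjusted p = 2.36e-08). Sulf2 rose by 3.82 ± 0.13 (14.1-fold, adjusted p = 1.16e-07), H2bc4 by 3.78 ± 0.23 (13.8-fold, adjusted p = 3.67e-06) and Cd80 by 3.46 ± 0.13 (11-fold, adjusted p = 1.44e-07). Untreated levels of Dcn (3.72), Ces2e (3.69) and Ptprv (3.93) lay near 3.65, the median of leukocyte markers, and a fold from or to that floor understates the change. By limma 4372 genes changed, 2360 higher and 2012 lower, of which 1410 and 1263 by at least 1.5-fold. Without 96 h replicate 1 the higher genes numbered 1560.

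All 46 DNA replication and S phase genes and all 51 mitosis and G2/M genes fell at 96 h, over all genes and adjusted over the list alone. Their medians were -2.70 (camera adjusted p = 2.01e-51, and adjusted p = 0.0806 with an estimated correlation) and -2.84 (2.14e-58, and adjusted p = 0.0806 with an estimated correlation). Dnmt1, the maintenance DNA methyltransferase, fell by 2.18 ± 0.06, Tpx2 by 2.99 ± 0.07, the chromosome-associated kinesin gene Kif4 by 3.36 ± 0.10 and Bub1b by 4.19 ± 0.12. Of 24 G1 cyclins and cell cycle inhibitors, 7 rose and 6 fell (7 and 7 adjusted over the list alone), with a median of 0.02 and a mean of -0.10, and the list was not called. Cdkn1a was not among these 24. Skp2, part of the ligase that degrades p27, fell by 2.38 ± 0.13 and Rbl1, the pocket protein p107, by 1.66 ± 0.11, while cyclin D2 (Ccnd2) rose by 0.78 ± 0.10. All 20 cholesterol genes fell (20 adjusted over the list alone), with a median of -2.09 (2.16e-22, and adjusted p = 0.12 with an estimated correlation), and Idi1 fell by 3.15 ± 0.12 (8.85-fold, adjusted p = 2.03e-07).

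The p53 target and lysosome lists were called higher at 96 h by camera with its preset correlation, and most of their members rose singly. Of 34 p53 targets, 23 rose and 1 fell (25 and 1 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 6.5e-13, and adjusted p = 0.0955 with an estimated correlation). Trp53inp1, a p53-induced nuclear protein, rose by 3.29 ± 0.17 (9.75-fold, adjusted p = 1.06e-06), Polk, a translesion DNA polymerase, by 1.78 ± 0.13 (3.43-fold, adjusted p = 1.28e-05) and Ercc5 by 1.76 ± 0.08 (3.39-fold, adjusted p = 5.02e-07). The member that fell was Sesn1 (-0.96 ± 0.13, adjusted p = 0.000637), chosen after its values were seen. Of 36 lysosome and autophagy genes, 20 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 0.61 (2.27e-08, and adjusted p = 0.336 with an estimated correlation). Hexa rose by 1.66 ± 0.10, the autophagy receptor gene Sqstm1 by 1.45 ± 0.12, the protease gene Ctsd by 1.24 ± 0.13 and Atg12, which takes part in building autophagosomes, by 1.23 ± 0.10.

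The ATF4 and amino acid response list split at 96 h, with 7 members higher and 16 lower of 41 (the same counts adjusted over the list alone), a median of -0.10 and a camera adjusted p of 0.137. Atf4 (1.35 ± 0.08, adjusted p = 4.09e-06) and Ddit3 (2.64 ± 0.21, 6.22-fold, adjusted p = 1.86e-05) rose. The serine synthesis enzyme gene Psat1 fell by 1.47 ± 0.15 (adjusted p = 9.45e-05) and Mthfd1l, of mitochondrial one-carbon metabolism, by 1.32 ± 0.14 (adjusted p = 0.000112). At 48 h the log2 change of Psat1 was 0.00 and that of Mthfd1l 0.23, neither past the test. Of 22 aminoacyl-tRNA synthetase genes, 9 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.30 (0.000376, and adjusted p = 0.444 with an estimated correlation), and Vars fell by 1.05 ± 0.09 (adjusted p = 2.94e-05). Without 96 h replicate 1 the fallen ATF4 genes numbered 8 and the fallen synthetases 3.

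**Figure D2:**
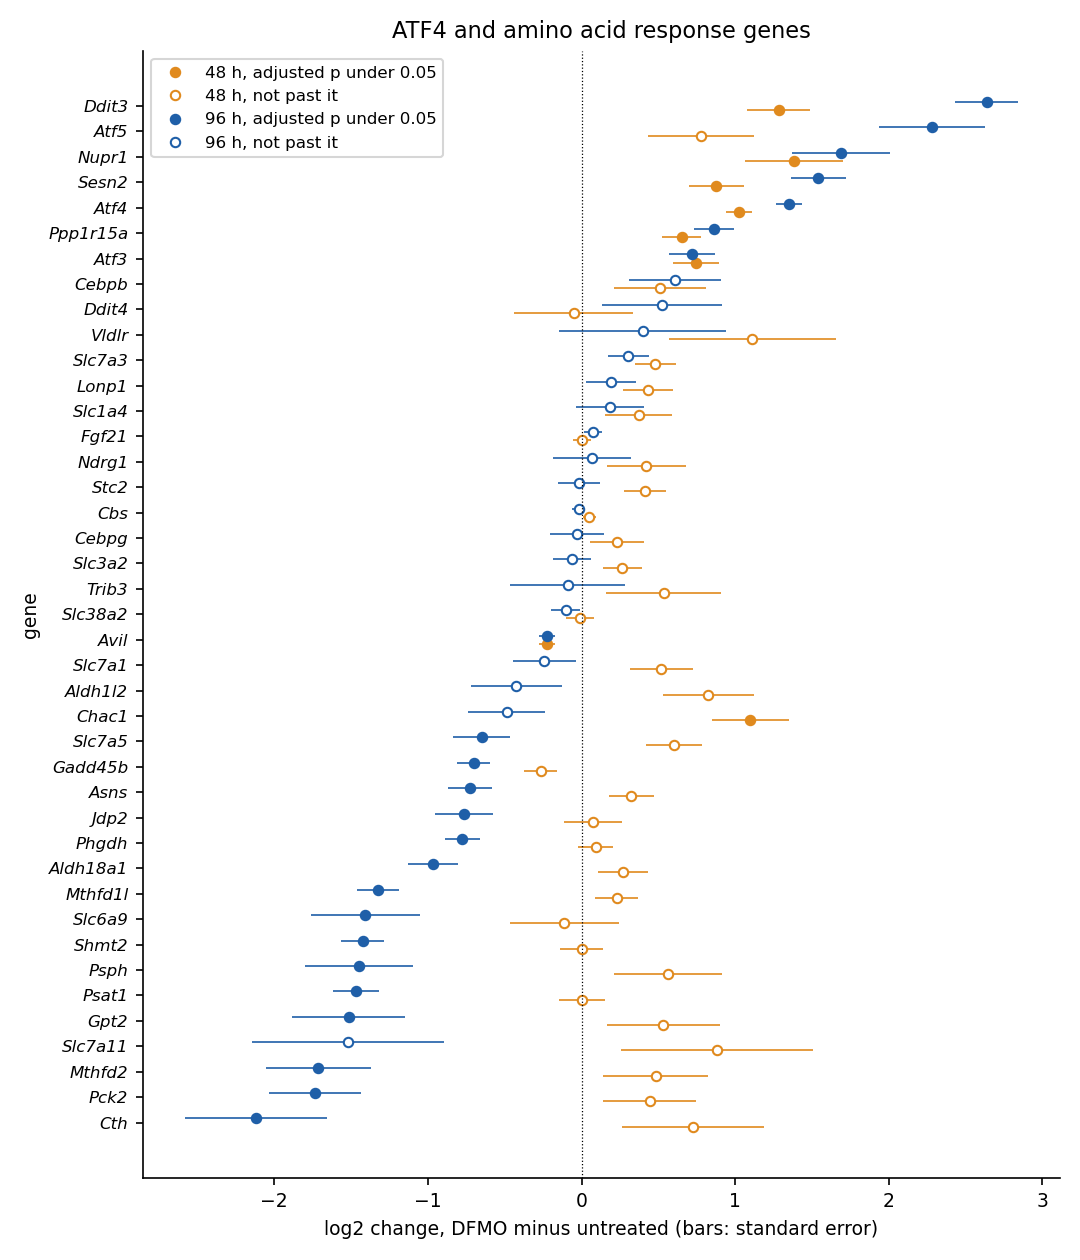
Log2 change against untreated, with its SE, of each member of the ATF4 and amino acid response list at 48 h and 96 h; filled points passed the adjusted threshold of 0.05. At 96 h 7 members lie to the right of 0 and 16 to the left among those that passed.

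The ribosome biogenesis and heat shock lists were called lower at 96 h by camera with its preset correlation, with part of their members past the test singly. Of 41 ribosome biogenesis and MYC target genes, 16 fell and 2 rose (18 and 3 adjusted over the list alone), with a median of -0.29 (0.000376, and adjusted p = 0.64 with an estimated correlation). Lyar, a nucleolar growth regulator, fell by 1.44 ± 0.14 and nucleolin (Ncl) by 0.46 ± 0.08. Of 22 heat shock genes, 12 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.30 (0.000181, and adjusted p = 0.336 with an estimated correlation). Fkbp4, an HSP90 co-chaperone, fell by 1.21 ± 0.07, Hspa4l by 1.24 ± 0.13 and the mitochondrial chaperonin gene Hspd1 by 0.70 ± 0.08. In the unfolded protein response list 9 fell and 2 rose of 29 (9 and 3 adjusted over the list alone), with a camera adjusted p of 0.115, and the isomerase gene Pdia6 fell by 1.17 ± 0.13 while the sensor gene Atf6 rose by 0.53 ± 0.08. Without 96 h replicate 2 the fallen members numbered 8 for ribosome biogenesis, 6 for heat shock and 5 for the unfolded protein response.

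Metabolic lists moved in part at 96 h. Of 31 glycolysis and hypoxia genes, 11 fell and 4 rose (15 and 5 adjusted over the list alone), with a median of -0.36 (0.00332, and adjusted p = 0.444 with an estimated correlation). Pdk1, a pyruvate dehydrogenase kinase, fell by 1.29 ± 0.12, P4ha2, a collagen prolyl hydroxylase subunit, by 1.30 ± 0.15 and Pgk1 by 0.69 ± 0.08, while neuronal enolase (Eno2) rose by 0.78 ± 0.08. Of 33 NRF2 and oxidative stress genes, 12 fell and 5 rose (13 and 5 adjusted over the list alone). The list was not called by camera (0.0711) but was by the directional test of fry (adjusted p = 0.00576). The quinone reductase gene Nqo1 fell by 2.74 ± 0.20 (6.66-fold, adjusted p = 1.32e-05), and Tkt, transketolase of the pentose phosphate pathway, by 1.56 ± 0.09. Of 20 adipocyte genes, 6 fell and 1 rose, with the same counts adjusted over the list alone, a median of -0.11 and a mean of -0.43 (0.00239, and adjusted p = 0.161 with an estimated correlation). The member that rose was Plin2 (1.10 ± 0.18), which coats lipid droplets and was chosen after its values were seen, and Elovl6 fell by 2.36 ± 0.14. The fallen glycolysis genes numbered 7 and 5 without 96 h replicates 1 and 2, and the risen ones 2 without untreated replicate 1 and 2 without 96 h replicate 1.

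Matrix, cytoskeletal and signalling lists were not called at 96 h, although single members changed. Of 44 extracellular matrix genes, 7 rose and 7 fell (8 and 7 adjusted over the list alone), with a median of 0.00. Besides Dcn, Col12a1, a fibril-associated collagen, rose by 1.58 ± 0.24 and fibronectin (Fn1) by 0.71 ± 0.12. The largest falls, chosen after their values were seen, were those of the elastin gene Eln, with a log2 change of -4.16 ± 0.76 (17.9-fold, adjusted p = 0.00321, and -3.57 and -4.76 without 96 h replicates 1 and 2), and of Col6a3, a microfibrillar collagen, with -1.48 ± 0.22 (adjusted p = 0.000897). Of 27 genes responsive to SRF, YAP and TGF-beta, 9 fell and 0 rose (9 and 1 adjusted over the list alone), with a median of -0.22, and calponin 2 (Cnn2) fell by 0.89 ± 0.12 and beta-actin (Actb) by 0.44 ± 0.08. Of 33 interferon-stimulated genes 6 rose and 3 fell (6 and 3 adjusted over the list alone), with Tap1, a peptide transporter of antigen presentation, at 1.52 ± 0.20. Of 31 immediate early genes 7 rose and 3 fell (7 and 4 adjusted over the list alone), with Klf6 at 0.89 ± 0.12 and Jun at 0.92 ± 0.10, and of 26 NF-kB and inflammatory genes 2 rose and 1 fell (2 and 1 adjusted over the list alone). Without 96 h replicate 2 the fallen matrix genes numbered 4, the fallen SRF and YAP genes 2, with 3 higher and a list median of 0.04, and the risen interferon genes 2. The 3 fallen interferon genes numbered 0 without untreated replicate 1, untreated replicate 2 or 96 h replicate 1, and 1 without 96 h replicate 2. The fallen SRF and YAP genes numbered 5 without untreated replicate 2, and the risen immediate early genes 4 without untreated replicate 1 and 3 without 96 h replicate 1.

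Few markers of other cell types changed. Of 20 macrophage and leukocyte markers 0 changed at 48 h, and at 96 h 1 rose, the lysozyme gene Lyz2 (1.90 ± 0.30, adjusted p = 0.00137). Of 20 epithelial and endothelial markers 0 changed at 48 h, and at 96 h Cdh1 (0.58 ± 0.07) and Tek (0.34 ± 0.06) rose while Krt14 fell by 1.82 ± 0.24. Krt14 was far from low in untreated cells (8.56, 8.76 and 9.17). Tek reached only 3.69 and 3.73 at 96 h, near the untreated median of leukocyte markers (3.65). Adjustment over each list alone gave the same counts, and neither list was called at any time.

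**Figure D3:**
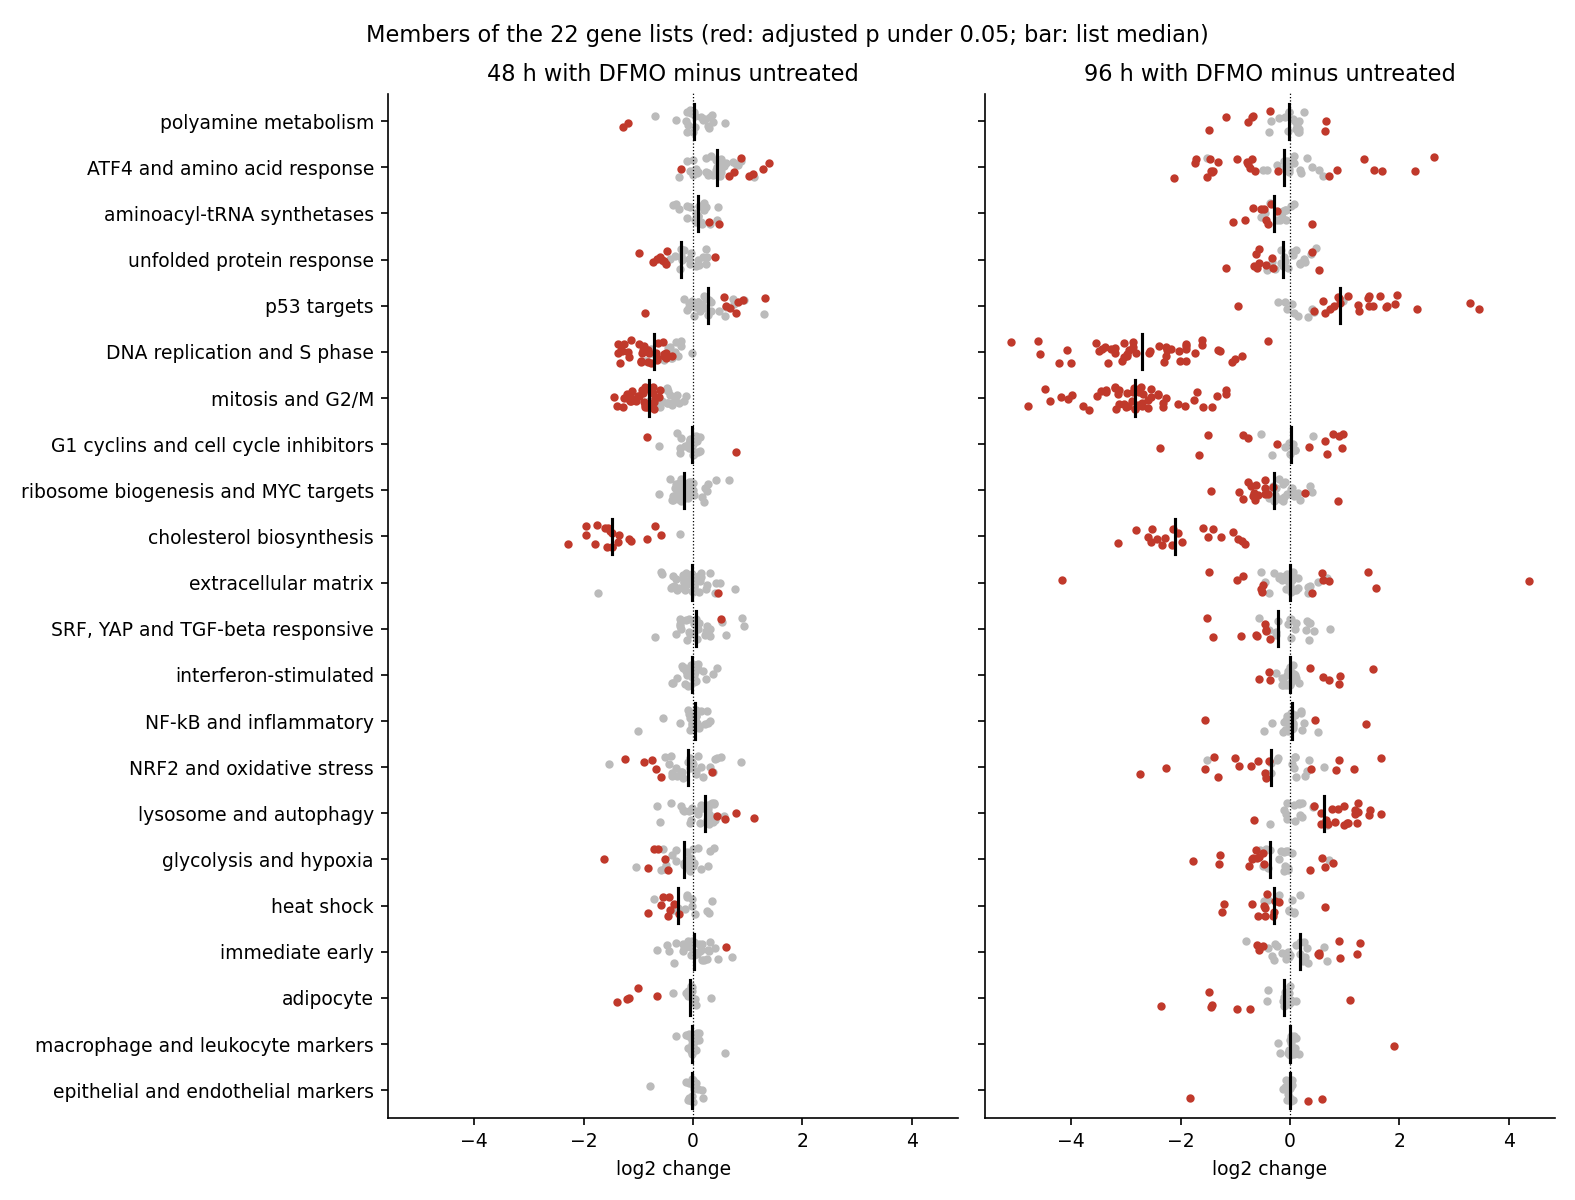
Log2 change against untreated of every measured member of the 22 gene lists at 48 h and 96 h, with genes past an adjusted p of 0.05 in red and a bar at each list's median. The replication, mitosis and cholesterol lists lie to the left of 0 at both times, with medians of -2.70, -2.84 and -2.09 at 96 h.

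Between 24 h and 48 h, the first step with changed genes, 16 of 20 cholesterol genes fell and 0 rose (20 and 0 adjusted over the list alone), with a median of -1.12. Nsdhl fell by 1.66 ± 0.18 (SE, limma adjusted p = 0.00314, n = 2 against 3), Hmgcs1 by 1.57 ± 0.16 (adjusted p = 0.00314) and Idi1 by 1.54 ± 0.12 (adjusted p = 0.0012), while Sulf2 rose by 1.73 ± 0.13 (adjusted p = 0.0012). The other largest rises, Chac1, a glutathione-degrading enzyme gene (1.34 ± 0.25, adjusted p = 0.0334), and H2bc4 (1.31 ± 0.23, adjusted p = 0.0244), were less stable. The Chac1 call was lost without untreated replicate 1 (1.34), 24 h replicate 1 (1.28) or 2 (1.26), 48 h replicate 1 (1.10) or 2 (1.58), or 96 h replicate 1 or 2 (1.34 without either). That of H2bc4 was lost without 24 h replicate 2 (1.22) or 3 (1.19) or 48 h replicate 1 (1.22) or 2 (1.40), and under the replicate block (1.33). Of the replication genes 25 fell and of the mitosis genes 26 (43 and 43 adjusted over the list alone), with 0 higher in either. In this step 333 genes changed, 105 higher and 228 lower, against 0 between 12 h and 24 h by limma, where 401 had an unadjusted p under 0.05. Under the replicate block 196 were higher and 242 lower from 24 h to 48 h. The count of 333 was 214 without 24 h replicate 3 and 92 and 67 without replicates 1 and 2 of the 48 h group, and 61 with only the arrays of the 2 times fitted. Without 48 h replicate 1 and without 48 h replicate 2 the fallen genes numbered 8 and 9 for cholesterol, 10 and 4 for replication and 10 and 7 for mitosis, and without 24 h replicate 3 those for replication 14.

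Between 48 h and 96 h the replication and mitosis genes fell further. Of them 43 of 46 and 51 of 51 fell (45 and 51 adjusted over the list alone), with 0 higher and medians of -1.90 and -2.06. Pclaf fell by 4.79 ± 0.20 (SE, limma adjusted p = 1.26e-06, n = 2 against 2), Uhrf1 by 4.43 ± 0.14 (adjusted p = 3.42e-07) and Mcm6 by 4.10 ± 0.09 (adjusted p = 2.85e-08). Ces2e rose 16-fold (SE 0.21 on the log2 scale, adjusted p = 4.82e-06), Dcn by 3.59 ± 0.34 (adjusted p = 0.000201) and Ptprv by 3.42 ± 0.10 (adjusted p = 3.42e-07). Of the 20 cholesterol genes 10 fell further and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.59. Among p53 targets 14 rose and 0 fell (20 and 1 adjusted over the list alone), and among lysosome genes 12 rose and 0 fell (19 and 0). In the ATF4 list 15 of 41 members fell and 2 rose in this step (20 and 4 adjusted over the list alone), and 9 of 22 synthetase genes fell with 0 higher (13 and 0). In all 1723 genes changed, 868 higher and 855 lower, and with centred arrays 731 and 974. The count was 748 without 48 h replicate 1, 1060 without 48 h replicate 2, and 1007 and 993 without replicates 1 and 2 of the 96 h group. Without 48 h replicates 1 and 2 and 96 h replicates 1 and 2 in turn, the fallen cholesterol genes numbered 3, 3, 3 and 6 and the risen lysosome genes 3, 9, 5 and 6. The p53 count was 9 without 48 h replicate 2, the ATF4 fall 9 without 48 h replicate 1, and the synthetase count 3 without 48 h replicate 1 and 3 and 4 without 96 h replicates 1 and 2.

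Of the 1160 genes changed at 48 h, 1002 had also changed at 96 h, 1000 in the same direction, with 466 higher and 534 lower at both times where independent lists would share 62.5 and 63.8. Across genes the log2 changes at 48 h and 96 h correlated with r = 0.753, against a mean of 0.401 in 100 simulations of unchanged groups with these controls, and the covariance was 0.0968 against 0.00695. The 24 h and 48 h changes had r = 0.619 against 0.447 simulated, with a covariance of 0.0198 against 0.00691, and the 12 h and 24 h changes r = 0.63 against 0.447, with 0.00926 against 0.00691. The 24 h and 96 h changes had r = 0.284 against 0.447, with 0.0183 against 0.00691, and the 12 h and 48 h changes r = 0.351 against 0.402, with 0.0103 against 0.00698. The 12 h and 96 h changes had r = 0.126 against 0.4, with a covariance of 0.00743 against 0.00693. The simulated groups are unchanged, whereas 1160 genes changed at 48 h and 4372 at 96 h, which widens the spread of those changes and lowers r. The simulated r is therefore no fair reference for 12 h or 24 h paired with these times. An r below it does not show less agreement than in unchanged groups. For 12 h and 24 h, r was 0.431 without 24 h replicate 3, 0.444 and 0.471 without 12 h replicates 1 and 2, and 0.762 without untreated replicate 3. The simulated arrays vary independently, whereas untreated replicate 3, 12 h replicate 2 and 24 h replicate 3 deviated together (r of 0.209 to 0.581). Deviations of same-number arrays of 24 h and 48 h also correlated (0.35 for replicate 1 and 0.419 for replicate 2). Without 12 h replicate 1 the r of 12 h was 0.13 with 48 h and -0.035 with 96 h, the latter being 0.266 without 12 h replicate 2 and 0.204 without untreated replicate 1. The 3 untreated arrays could not be split into parts of at least 2, so part of each excess may come from the shared controls. These correlations are across genes, which are not independent replicates. A test of any change over the 4 times called 3395 genes, and 2023 without 96 h replicate 1 or 2029 without 96 h replicate 2.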

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

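All tests of explanations in this part were chosen only after the result was seen, except that of the snoRNA host transcripts.

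Effects differed between times by the test of each step. Between 24 h and 48 h 333 genes differed, and between 48 h and 96 h 1723. Of the genes past the threshold at both 48 h and 96 h, 2 had opposite directions with the step between them also past it. Mylip, a ubiquitin ligase that degrades the LDL receptor, fell by 0.71 ± 0.15 at 48 h (limma adjusted p = 0.027) and rose by 0.55 ± 0.15 at 96 h (adjusted p = 0.0278). The call at 48 h was lost without untreated replicate 1 (-0.68) or 2 (-0.66) or 48 h replicate 1 (-0.65) or 2 (-0.77), and that at 96 h without untreated replicate 1 (0.57) or 3 (0.48) or 96 h replicate 1 (0.60) or 2 (0.50). Wars, the tryptophanyl-tRNA synthetase gene, was at 0.29 ± 0.07 (adjusted p = 0.0349) and then -0.25 ± 0.07 (adjusted p = 0.0263). Its call at 48 h was lost without 1 of 7 arrays, among them each untreated array (0.29, 0.32 and 0.27 without replicates 1, 2 and 3) and each 48 h array (0.24 and 0.34). At 96 h it was lost without untreated replicate 1 (-0.25), untreated replicate 2 (-0.22), or 96 h replicate 1 or 2 (-0.25 without either).

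Clusters that name no single gene, and so lay outside the gene tests, also changed. With all clusters tested together, 222 of them passed at 48 h, 174 with no symbol and 48 with several. At 96 h 1070 passed, 790 with no symbol and 280 with several.

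All 46 replication genes and all 51 mitosis genes fell at 96 h although the cells had been sorted for G1. A smaller share of S phase cells in the sorted fraction stays open as the cause. Histone genes were compared because their transcripts are made mostly in S phase, and 6 of them with untreated levels of at least 6 had a median log2 change of -0.51 (quartiles -0.98 and 0.04), which is 2.19 above the -2.70 of the replication list. That difference decides nothing, since 1 of the 6, H4c9, rose by 1.41 ± 0.12, and signals that rise while all replication genes fall do not measure the share of S phase cells. Fewer G2 and M cells in the fraction may also contribute, since nothing separates that from lower expression in each cell (median -2.84 for the mitosis list), and time in culture stays open because 0 untreated arrays were collected at 96 h.

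The ATF4 list moved in both directions at 96 h, with 7 members higher and 16 lower. A single factor per array would move all members alike, and the split itself argues against it as the whole cause. The 9 members more than 3 SE above the list's median change and the 14 more than 3 SE below it largely restate that split and are not separate support. This test and the next replaced earlier ones that had decided nothing, after the values of those had been seen. That the fallen members are dim genes near the floor is argued against as well, because at 96 h they still had a median level 4.06 above that of leukocyte markers in untreated cells (quartiles 1.97 and 5.41), although 1 of the 16 lay within 1 log2 unit of that floor. A candidate explanation on the side of the cells is slower nonsense-mediated decay, which would raise Atf4, Ddit3 and snoRNA host transcripts. That test decided nothing, as 2 of 11 hosts had a cluster of their own (Snhg5 at 0.32 ± 0.11 and Snhg15 at -0.06 ± 0.29, median 0.13), and time in culture could not be separated from DFMO.

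Untreated replicate 3, 12 h replicate 2 and 24 h replicate 3 deviated from their groups together, with r of 0.209 to 0.581 between their deviations. The deviations of the 2 arrays at 12 h mirror each other. So 12 h replicate 1 had r of -0.318 with untreated replicate 3 and -0.209 with 24 h replicate 3, against 0.318 and 0.209 for replicate 2. These r cannot tell which of the 12 h arrays deviated. As a common offset the 3 arrays differed in 547 genes (343 higher and 204 lower), and the highest count for the other choices of 1 array per group was 0. These arrays were picked from the data, and 18 choices are too few for a share under 0.05, so that chance is not tested by this. RNA integrity or labelling that acts by gene length may contribute and stays open. The offset correlated with genomic span across genes (Spearman rho = -0.177), but another choice of arrays gave -0.183. Genomic span includes introns and is not the length of the transcript, so this correlation cannot decide it. No batch is given in the labels, and no biological explanation was tested.

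The count at 24 h against untreated was 0, and the highest count for the other splits of these 6 arrays into 3 and 3 was 1. As no split can give fewer than 0, all 10 splits gave at least as many genes, which says nothing, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 limma gave 1579 genes for the real split and up to 2354 for the others. The 4 splits that part all 3 same-number pairs gave 1579 (the real one), 586, 438 and 427, and the 2 splits above the real one, with 1858 and 2354, part 1 pair each.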

How the results depend on the processing

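The alternatives that treat untreated replicate 3, 12 h replicate 2 and 24 h replicate 3 together were chosen only after the result was seen, and all others were planned. With 2 or 3 arrays a group, a group of 2 loses its own spread when 1 is left out, and the lone array is assumed to vary like the others. Signals near the array's floor limit folds for dim genes, whatever the setting. The cause was not tested for any change given here, except that a stricter threshold calls fewer genes by its construction.

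The count of 0 genes at 24 h became 11 with all clusters tested together, and stayed 0 in every other setting. For 48 h, the 1160 genes became 2194 with array weights, 585 with a fold of at least 1.5, 353 at an adjusted p under 0.01, and 375 to 1265 with 1 array left out. For 96 h, the 4372 genes became 2673 with the fold and 2893 at the stricter p. The 333 genes between 24 h and 48 h became 521 with array weights, 217 with all clusters, 61 with only the groups compared, 215 with the fold, 78 at the stricter p, and 67 to 418 with 1 array left out. The 1723 between 48 h and 96 h became 1081 with the fold, 783 at the stricter p, and 748 to 1849 with 1 array left out. The 3395 genes changed at any time became 1946 at the stricter p and 2023 to 3577 with 1 array left out. Total counts under all other settings stayed within 1.5 times, but not the counts by direction. Under the replicate block the genes higher at 48 h numbered 810 against 528, and those higher between 24 h and 48 h 196 against 105, the latter being 158 with the 3 arrays as a batch block. Without 96 h replicate 1 the genes higher at 96 h numbered 1560 against 2360. With the 3 arrays as a batch block 1508 genes changed at 48 h and 4795 at 96 h, and with them left out 1155 and 4394.

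With a correlation estimated per list, camera called 0 lists at each of 12, 24, 48 and 96 h, against 2, 7, 10 and 10. The directional test of fry called 0, 1, 10 and 10 lists at these times, and its mixed test 0, 6, 18 and 22. Its directional test did not call the lysosome list at 48 h (adjusted p = 0.151) or ribosome biogenesis at 96 h (0.0545). It did call the NRF2 list at 48 h (0.0433) and 96 h (0.00576). At 12 h the number called by camera was 4 with the replicate block, 6 without dim genes and 4 with centred arrays. It was 4 with the 3 arrays as a block, 5 with them left out, and 2 to 7 with 1 array left out. It was 4 to 7 at 24 h with 1 array left out. With the 3 arrays left out, the unfolded protein response list at 12 h changed sign, with an adjusted p of 0.576. Of 29 list calls, 19 held in fry's directional test, 28 under the replicate block, 28 without dim genes and 28 with centred arrays. With the 3 arrays as a block 29 held. With them left out 27 held, 1 was lost and 1 changed sign.

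Whether equal replicate numbers pair the arrays is open. For 24 h against untreated some pairs of unlike number also correlated above 0.1, and in the other comparisons only 2 numbers are shared. The r of the same-number pairs with untreated arrays were 0.189 and -0.255 at 12 h, -0.075 and 0.157 at 48 h and -0.136 and -0.08 at 96 h. Between treated times they were 0.054 and -0.149 for 12 h and 24 h, 0.35 and 0.419 for 24 h and 48 h, 0.035 and 0.02 for 24 h and 96 h, 0.12 for both pairs of 12 h and 48 h, 0.148 for both of 12 h and 96 h and -0.049 for both of 48 h and 96 h. In a group of 2 arrays the deviations mirror each other (r of -1). Between 2 such groups both pairs therefore have the same r by construction, and the pairs of unlike number have its negative. Over 21 same-number pairs of different groups the deviations correlated with r of -0.255 to 0.581, and over 36 other pairs with -0.423 to 0.318. For the same reason these pairs are not all separate values. Under the replicate block limma called 0, 0, 1542 and 4778 genes at 12, 24, 48 and 96 h, with 1748, 2040, 4417 and 6335 at an unadjusted p under 0.05. Of the 1160 genes, 1016 kept their call, and of the 4372, 4096. Under the block the risen members numbered 12 for p53 targets and 8 for lysosome genes at 48 h, and 11 for immediate early genes at 96 h. Apart from the list calls above, H2bc4 between 24 h and 48 h (1.33) and Ifit2 at 96 h (-0.52) lost their calls, out of 187 calls of named genes tested again.

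Of these 187 calls, which include those of 16 genes chosen after their values were seen, 143 held without any 1 array and 44 were lost without at least 1, all without a change of sign. Of the same 187, 181 held with trend and robust on, 187 with centred arrays, 185 after quantile normalisation again, 185 with the 3 arrays as a block and 174 with them left out. With 1 array left out, r between times ranged from 0.431 to 0.762 for 12 and 24 h, 0.13 to 0.447 for 12 and 48 h, -0.035 to 0.266 for 12 and 96 h, 0.505 to 0.657 for 24 and 48 h, 0.232 to 0.346 for 24 and 96 h and 0.659 to 0.768 for 48 and 96 h.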

Other observations

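The comparison of histone genes and the genes named in this part, other than H2bc4, Ddit3 and the hosts Snhg5 and Snhg15, were chosen only after the result was seen.

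Histone genes, which were in no list, moved in both directions at 96 h. Of 26 measured, 7 rose and 3 fell by limma, and of the 6 with untreated levels of at least 6, 1 rose and 3 fell. H2bc4 (3.78 ± 0.23, adjusted p = 3.67e-06), H1f2 (3.11 ± 0.17, adjusted p = 1.54e-06) and H2bc8 (2.03 ± 0.29, adjusted p = 0.000822, 2.71 and 1.35 without 96 h replicates 1 and 2) were among those that rose, and H1f5 fell by 1.41, a call lost without 96 h replicate 1 (-1.44) or 2 (-1.39). The 22 replication genes within the same range of untreated levels as the 6 brighter histones, 6.07 to 8.39, had a median of -2.86 and a highest value of -1.07. The difference of 2.19 between the medians of the brighter histones and of the replication list does not measure the share of S phase cells, since histone signals also rose.

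Among the 7 members of the ATF4 list that rose at 96 h were Atf5 (2.28 ± 0.34), Nupr1 (1.69 ± 0.32) and Ddit3 (2.64 ± 0.21). Among the 16 that fell were Cth at -2.12 ± 0.46 (lost without 96 h replicate 1 at -1.65), Pck2 at -1.74 ± 0.30 and Asns, the asparagine synthetase gene, at -0.72 ± 0.14. Gas5, a snoRNA host transcript whose level depends on nonsense-mediated decay, rose by 0.78 ± 0.12 at 48 h (limma adjusted p = 0.00777, lost without 48 h replicate 1 at 0.59) and 0.98 ± 0.12 at 96 h (adjusted p = 0.000385). The 2 other host transcripts measured were not past the threshold at 96 h, with Snhg5 at an adjusted p of 0.0741 and Snhg15 at 0.939.

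Mdm2, a p53 target whose product limits p53, rose by 1.91 ± 0.16 at 96 h (3.76-fold, limma adjusted p = 2.39e-05), from 0.60 ± 0.16 at 48 h (adjusted p = 0.0571).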
